A study of Mus musculus with 42 samples.

How the data were processed

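Libraries came from purified splenic B cells of mice on the BL6 background that carry preassembled IgH and Igκ loci, cultured with anti-CD40 (1 ng/mL) and IL-4 (20 ng/mL), per the labels' protocols; a slip in the unit of the anti-CD40 dose was not ruled out. The protocols name a single culture length of 4 days, while the titles of 6 libraries give day 3, and the titles were followed. Per the labels' protocols, genomic DNA was linearly amplified from a biotinylated Sμ primer, amplified again by nested PCR, digested with AflII to remove germline product and sequenced on a MiSeq. This is high-throughput genome-wide translocation sequencing, in which the fixed Sμ end is the bait and the joined site the prey. Reads were aligned with Bowtie2 to mm9, per the submitters' processing notes; the version and the read filters are not given in the sources used here.

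The deposited workbooks hold, per library, the authors' junction counts by prey class and orientation and by overlap or insertion length, and the mm9 coordinate of each Sμ, Sγ1 and Sε junction, per the file headers. The counts are whole numbers with no normalization. No molecular identifiers are mentioned in the labels, so counts can hold copies of 1 molecule that the authors' filters kept. Prey on the minus strand of chromosome 12 was read as deletional and on the plus strand as inverted. The deposited overlap classes above 1 bp span several lengths, and class midpoints were used, with 15 bp for the open top class; in 15 libraries with exact lengths the midpoint mean exceeded the exact mean by 0.0365 to 0.123 bp. The authors also deposited pooled tables for the 13 groups; 12 equal the sum of their libraries, and the pooled table of WT cells marked Ai holds 4070 junctions, the sum of libraries 3 and 4.

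Groups and replicate numbers were taken from the titles. The core span of a region is the shortest run of bins (100 bp for Sγ1, 50 bp for Sε and Sμ) that holds 90% of its junctions with all 42 libraries weighted equally. The 14 secondary measures are the shares of blunt joins, of insertions and of overlaps of at least 4 bp, the shares of Sμ, Sγ1, Sε and other IgH prey, Sγ1 over Sγ1 plus Sε, the inverted share of each of the 3 regions, the Sε and Sμ shares outside their cores and the mean insertion length. Bait mutation frequency was not analysed here, because the sheets that hold it cover different prey regions. Single counts for the other switch regions were not used here. The groups, the tests, the measures, the rule for named loci and most alternatives were set before the data were examined. The loci named outside IgH are the 10 bins of 100 kb with junctions in the most libraries, ties ordered by junctions; a preset list of known off-target genes was not analysed here because no gene annotation on mm9 was used.

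Each library gave 1 value per measure. Groups were compared by the difference of means with an exact two-sided permutation test over all splits of the libraries, p-values were adjusted by Benjamini-Hochberg over the 4 primary or the 14 secondary measures of a comparison, and a difference was called at an adjusted p under 0.1. There were 8 comparisons of 2 groups. The 95% intervals of differences invert the same exact test. The trend over CTV fractions permuted fractions within each of 2 numbered cultures. Differences between effects used Freedman-Lane permutation of residuals with 100000 resamples. Shares of single libraries have Wilson 95% intervals. The trend of non-IgH count with yield is the slope of log non-IgH on log IgH count within groups over all 42 libraries, and its removal was chosen after the counts were seen. Sequencing runs, of which there were 6, were told apart by the instrument and run in the read names. Of the libraries, 3 held reads of more than 1 run and were left out of the within-run values. Only 5 to 79 named reads per library were used for this, so reads of a further run in the other libraries are not excluded.

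Replicates were compared first. Of 54 pairs within groups, 7 had counts over prey classes that agreed within sampling noise (chi-square p above 0.05), and none was merged. The densest sharing of switch positions among those pairs, counted per position pair, was below the densest between groups (290 against 310 on the same scale), a bound too wide to single out a pair within its group. Of the 6 with other pairs in their group, 2 shared more positions than the densest other pair there gives: WT Ai libraries 1 and 2 (40 against 27.8) and XRCC4-deleted day 3 libraries 1 and 2 (23 against 21.9). Whether equal replicate numbers pair libraries was checked by correlating the deviations of same-numbered libraries from their group means. For CtIP-deleted against WT cells all 4 correlations were above 0.1 (0.102 to 0.621, 3 libraries correlating best with their own number), so the paired values are given with that comparison; this pairing comes from the data and is not stated in the labels. In the other comparisons at least 1 correlation was 0.1 or lower.

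The alternatives covered leaving out each library, the replicate number as a block, log scale, a minimum of 500 junctions, within-run tests, overlaps of at least 2 or 6 bp, insertions counted as overlap 0, other denominators, core spans of 80% and 95%, only the downstream side of the core, non-IgH junctions on other chromosomes, both days or both genotypes together, all WT day 4 libraries as controls and the authors' pooled tables. Another 3 were added after the data were seen: non-IgH shares without overlaps of 10 bp or more and insertions over 10 bp, and WT Ai libraries 1 and 2 averaged or left out. The tests were run on simulated libraries with the observed spreads, 500 per comparison. Without an effect each single primary measure was called in at most 4.8% of simulations in each of the 8 comparisons. The rate of a call in at least 1 of the 4 was not counted, and the secondary measures were not simulated. Effects of the size seen in XRCC4-deleted against WT cells were then added to all 4 primary measures at once, with measures drawn independently. The non-IgH effect of 8.37 percentage points was called in 56% of simulations of the CtIP-deleted comparison. It was called in 49.2% for the double-deleted comparison and 27.2% for the XRCC4-deleted Ai comparison, the lowest. Calls on the other measures ease the adjustment, so these rates do not cover a non-IgH effect alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.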

Results

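Junctions between a break in the Sμ switch region of the mouse IgH locus and other genomic sites were sequenced from 42 libraries of activated splenic B cells in 13 groups. Class switch recombination joins breaks in Sμ to breaks in a downstream switch region, here Sγ1 or Sε under stimulation with anti-CD40 and IL-4. The wild-type (WT) groups were cells at day 3 (3 libraries) and day 4 (4 libraries), day 4 cells marked Ai (4 libraries) and day 4 cells in CTV fractions I, II, III and IV (2 libraries each). The other groups were CtIP-deleted cells (5 libraries), XRCC4-deleted cells at day 3 (3 libraries) and day 4 (5 libraries), XRCC4-deleted day 4 cells marked Ai (3 libraries), CtIP and XRCC4 double-deleted cells (4 libraries) and XRCC4-deleted cells with the CtIPA allele (3 libraries). The labels do not spell out Ai, the nature of the CtIPA allele or which CTV fraction divided more. The genotypes pair conditional alleles with CD21Cre, and loss of the target genes is not measured in junction data.

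The libraries held 68908 junctions, from 283 in fraction I of culture 1 to 4995 in fraction IV of culture 2. Junctions outside IgH numbered 75 to 366 per library and 8549 in all. The Wilson 95% interval of the share of junctions in Sγ1 or Sε had a half-width of 1.15 percentage points in the deepest library and 5.39 in the shallowest. Such intervals cover counting error only. The labels do not say that replicate libraries came from separate animals or cultures, so the p-values below measure the spread between these libraries, which may be technical. Each comparison had 4 primary measures: the mean overlap (microhomology) length at Sγ1 and Sε junctions without inserted bases, the share of all junctions in Sγ1 or Sε, the share of Sγ1 junctions outside the core span, and the share of junctions outside IgH. On chromosome 12 (mm9) the core spans, each holding 90% of a region's junctions, were 114570400 to 114576799 for Sγ1, 114512550 to 114515099 for Sε and 114661900 to 114665249 for Sμ.

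**Figure D1:**
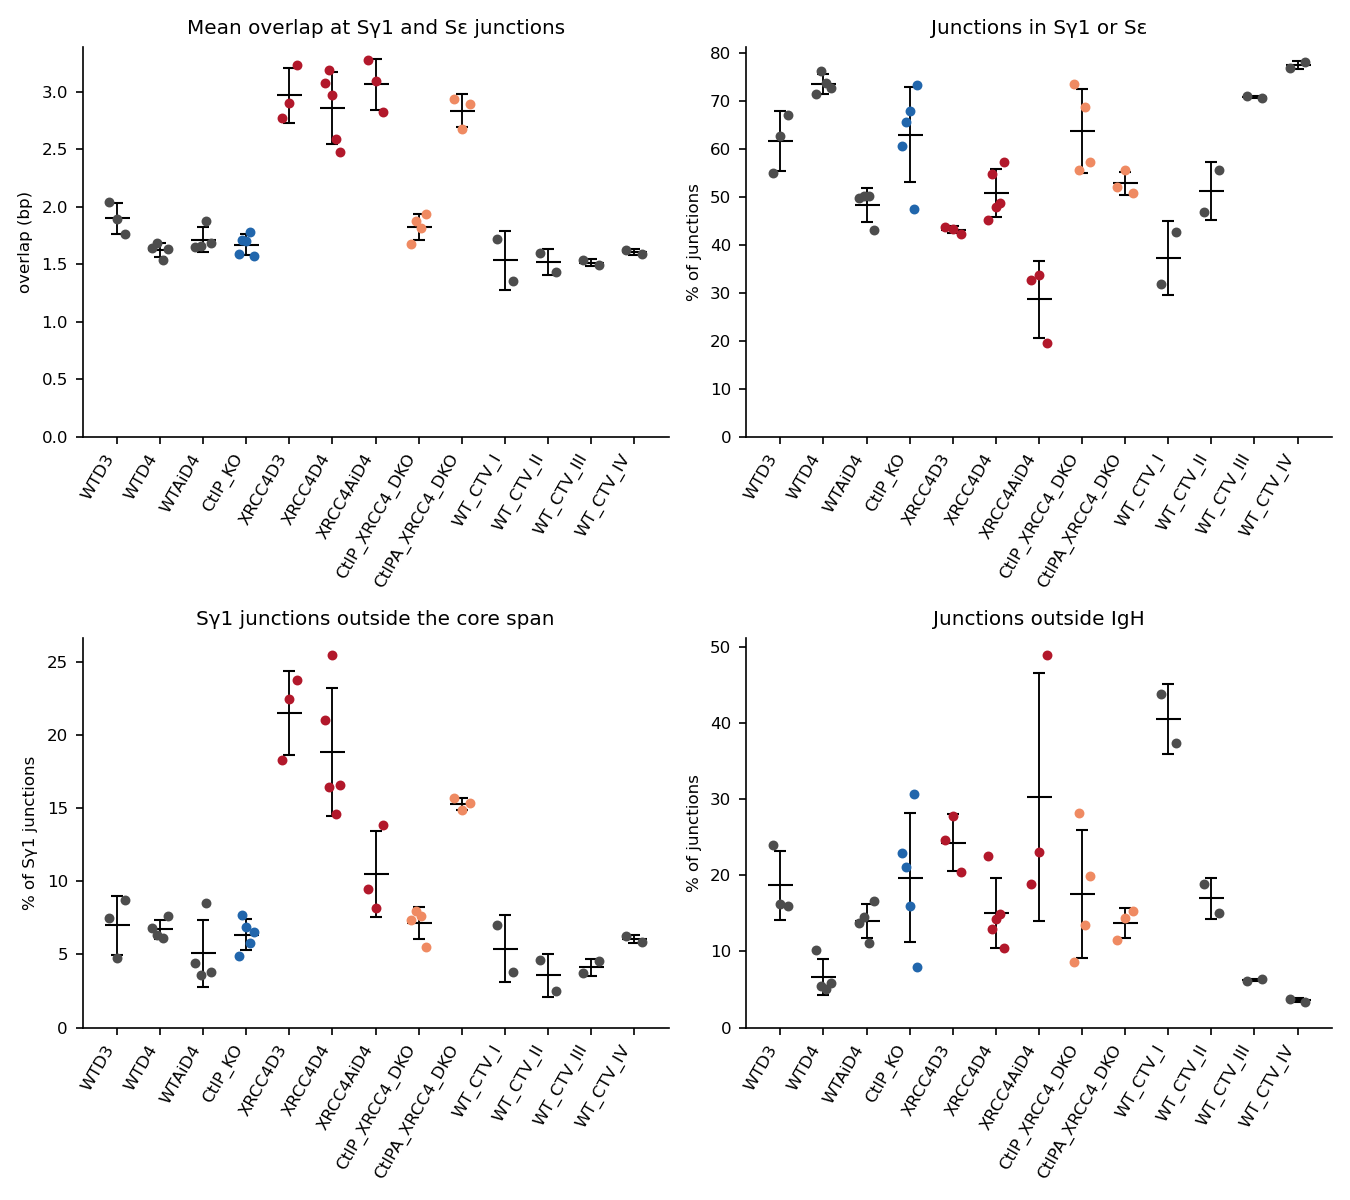
Primary measures per library for the 13 groups: mean overlap in bp, percent of junctions in Sγ1 or Sε, percent of Sγ1 junctions outside the core span and percent of junctions outside IgH, with points for libraries and bars for the mean and SD (lower bars end at 0). Mean overlap is 2.86 bp in day 4 XRCC4-deleted cells, 1.83 bp in double-deleted cells and 1.62 bp in WT day 4 cells.

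The comparison of XRCC4-deleted with WT cells at day 4 asks how junctions form without XRCC4, the partner of DNA ligase IV in classical end joining. Overlaps at Sγ1 and Sε junctions were longer, 2.86 ± 0.313 bp (SD, n = 5) against 1.62 ± 0.0607 bp (SD, n = 4) in WT, a difference of 1.24 bp (95% interval 0.841 to 1.56). Blunt junctions fell from 24.2 ± 1.87% to 11.6 ± 2.63%, and overlaps of at least 4 bp rose from 8.53 ± 0.897% to 24.8 ± 3.37%. The share of junctions in Sγ1 or Sε fell from 73.6 ± 2.04% to 50.8 ± 5.06%, and within it the Sε share of all junctions fell from 36.9 ± 2.29% to 11.3 ± 4.48%. Sγ1 itself held 39.5 ± 4.41% against 36.7 ± 1.73%, a difference within the spread between libraries.

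Junctions also spread out and changed orientation in XRCC4-deleted cells. Sγ1 junctions outside the core span rose from 6.71 ± 0.654% to 18.8 ± 4.39%, and Sμ junctions outside theirs from 7.26 ± 0.290% to 24.4 ± 7.00%. Inverted joins to Sγ1 rose from 7.96 ± 0.898% to 16.4 ± 4.51%. Junctions outside IgH rose from 6.65 ± 2.35% to 15.0 ± 4.57%. In the exact two-sided permutation test each primary measure gave p = 0.0159, the smallest p these 9 libraries allow, and an adjusted p of 0.0159, with all 5 XRCC4-deleted libraries on the same side of the WT mean. Of 14 secondary measures 13 passed at an adjusted p under 0.1, 10 higher and 3 lower. Within the sequencing runs that held both groups the differences were 1.21 bp, -22.6, 11.8 and 8.05 percentage points, each with an exact p of 0.0333, and in the single runs they were 0.948 and 1.42 bp for overlap. XRCC4-deleted libraries averaged 1311 junctions in IgH against 2918 in WT, and after removal of the trend of non-IgH count with yield the non-IgH count was 1.48 times that of WT with an exact p of 0.0794.

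**Figure D2:**
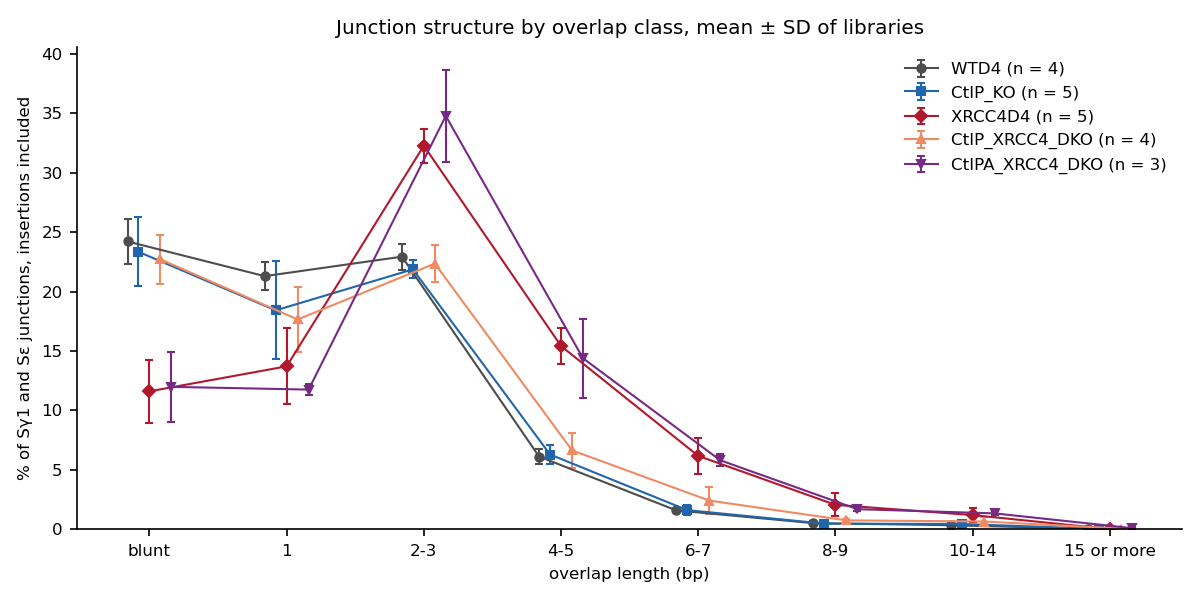
Percent of Sγ1 and Sε junctions in each overlap class (bp) for 5 day 4 groups, as mean and SD of libraries. Overlaps of 2-3 bp hold 32.3% of junctions in XRCC4-deleted and 22.9% in WT cells, and the double-deleted group lies near WT and CtIP-deleted cells in the classes above 1 bp.

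CtIP starts the resection of DNA ends, and the comparison of CtIP-deleted with WT day 4 cells asks whether its loss changes junctions when classical end joining is intact. Overlaps averaged 1.67 ± 0.0902 bp (SD, n = 5) against 1.62 ± 0.0607 bp (SD, n = 4), a difference of 0.0488 bp (95% interval -0.0812 to 0.167). Sγ1 junctions outside the core were 6.34 ± 1.07% against 6.71 ± 0.654%, a difference of -0.374 percentage points (95% interval -1.87 to 1.04). Junctions outside IgH were higher, 19.7 ± 8.47% against 6.65 ± 2.35%, and those in Sγ1 or Sε lower, 63.1 ± 9.86% against 73.6 ± 2.04%.

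In the exact permutation test overlap had p = 0.381 (adjusted p = 0.508) and the Sγ1 share outside the core p = 0.587. For the Sγ1 or Sε share the exact p was 0.0476 and for the non-IgH share 0.0317, both with an adjusted p of 0.0952 and all 5 CtIP-deleted libraries on that side of the WT mean. None of the 14 secondary measures passed in the exact permutation test, and 1, the Sγ1 share, had an unadjusted p under 0.05 (29.1 ± 3.22% against 36.7 ± 1.73%, exact p = 0.0159, adjusted p = 0.222). That is the smallest exact p these libraries allow, and 1 of 14 measures alone at it cannot pass the adjustment. The ranges of the groups did not overlap in the Sγ1 share. With junctions in IgH as the denominator the Sγ1 or Sε share differed by -0.643 percentage points (exact p = 1). With all WT day 4 libraries, CTV fractions included, as controls both calls ended, at -0.980 (permutation p = 0.867) and 6.26 percentage points (permutation p = 0.358). The 8 CTV libraries were counted there as independent, though they are sorted fractions of 2 cultures. Their Sγ1 or Sε share ran from 31.8% to 78.1%, so these differences depend on the mix of fractions and the p-values ignore the shared cultures. Within runs the differences were -5.80 (exact p = 0.133) and 8.67 percentage points (exact p = 0.0667, the smallest these libraries allow). In run 1, where library 5 was the only CtIP-deleted library, they were 0.123 and 2.40, and in run 2 -9.09 and 12.2. Paired by replicate number they were -13.1 and 16.0 percentage points, with an exact p of 0.125, the smallest that 4 pairs allow. CtIP-deleted library 5, with 73.4% of junctions in Sγ1 or Sε and 7.89% outside IgH, has no WT partner. The paired differences therefore equal the unpaired differences without that library. Without any 1 library, CtIP-deleted library 5 excepted, both calls ended, and without CtIP-deleted library 4 the Sγ1 or Sε difference was -6.64. CtIP-deleted libraries averaged 968.2 junctions in IgH, and with the yield trend removed the non-IgH count was 1.66 times that of WT with an exact p of 0.0635.

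The comparison of double-deleted with XRCC4-deleted day 4 cells asks whether the junctions seen without XRCC4 need CtIP. Overlaps were shorter in the double-deleted cells, 1.83 ± 0.113 bp (SD, n = 4) against 2.86 ± 0.313 bp (SD, n = 5), a difference of -1.03 bp (95% interval -1.39 to -0.622). Sγ1 junctions outside the core were 7.13 ± 1.10% against 18.8 ± 4.39%, and Sμ junctions outside theirs 7.13 ± 2.01% against 24.4 ± 7.00%. Blunt junctions were 22.7 ± 2.07% against 11.6 ± 2.63%, and inverted joins to Sγ1 8.11 ± 1.96% against 16.4 ± 4.51%. The Sε share was 33.1 ± 11.2% against 11.3 ± 4.48%, and the Sμ share 17.9 ± 2.78% against 31.5 ± 2.09%. Sγ1 held 49.1 ± 10.7% of Sγ1 and Sε junctions against 77.9 ± 7.37%, so part of the overlap difference can come from this shift of prey. Within Sγ1 the overlap was 1.99 ± 0.103 bp against 3.09 ± 0.245 bp, and within Sε 1.66 ± 0.107 bp against 2.04 ± 0.287 bp.

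Overlap and the Sγ1 share outside the core each had an exact permutation p of 0.0159 (adjusted p = 0.0317), and all 4 double-deleted libraries lay below all XRCC4-deleted ones. The Sγ1 or Sε share was 13.0 percentage points higher, 63.8 ± 8.81% against 50.8 ± 5.06% (exact p = 0.0476, adjusted p = 0.0635), and the non-IgH share differed by 2.51 percentage points (95% interval -7.70 to 13.8, exact p = 0.619). Of 14 secondary measures 11 passed, 3 higher and 8 lower. Within runs the differences were -1.10 bp, 15.6, -11.4 and 1.25 percentage points, where the smallest exact p is 0.0667. In run 1, which held 1 double-deleted library, they were -0.856 bp for overlap and -4.08 percentage points for the non-IgH share. In run 2 they were -1.23 bp and 4.21 percentage points. The sign of the non-IgH difference also turned with some single libraries left out. The call on the Sγ1 or Sε share was lost with junctions outside Sμ as the denominator (3.55 percentage points, exact p = 0.492). It was also lost without double-deleted library 1 (9.75) or 3 (11.3), or without XRCC4-deleted library 1 (11.6), 2 (14.0), 3 (12.3) or 4 (12.5).

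The effect of CtIP deletion differed with XRCC4 status in 3 of the 4 primary measures. The effect with XRCC4 loss minus that without was -1.08 bp for overlap (permutation p = 8e-05, adjusted p = 0.00032), -11.3 percentage points for the Sγ1 share outside the core (permutation p = 0.00023, adjusted p = 0.00046) and 23.6 percentage points for the Sγ1 or Sε share (permutation p = 0.00317, adjusted p = 0.00423). For the non-IgH share it was -10.5 percentage points (permutation p = 0.112), which did not pass, but did on the log odds scale (-1.06, permutation and adjusted p = 0.0418) and as a share of junctions outside Sμ (-15.9, permutation and adjusted p = 0.0601). The Freedman-Lane test treats residuals of all groups as exchangeable and ignores run. The SD of overlap ran from 0.0607 bp in WT to 0.313 bp in XRCC4-deleted cells. How often the test calls without an effect was not simulated.

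**Figure D3:**
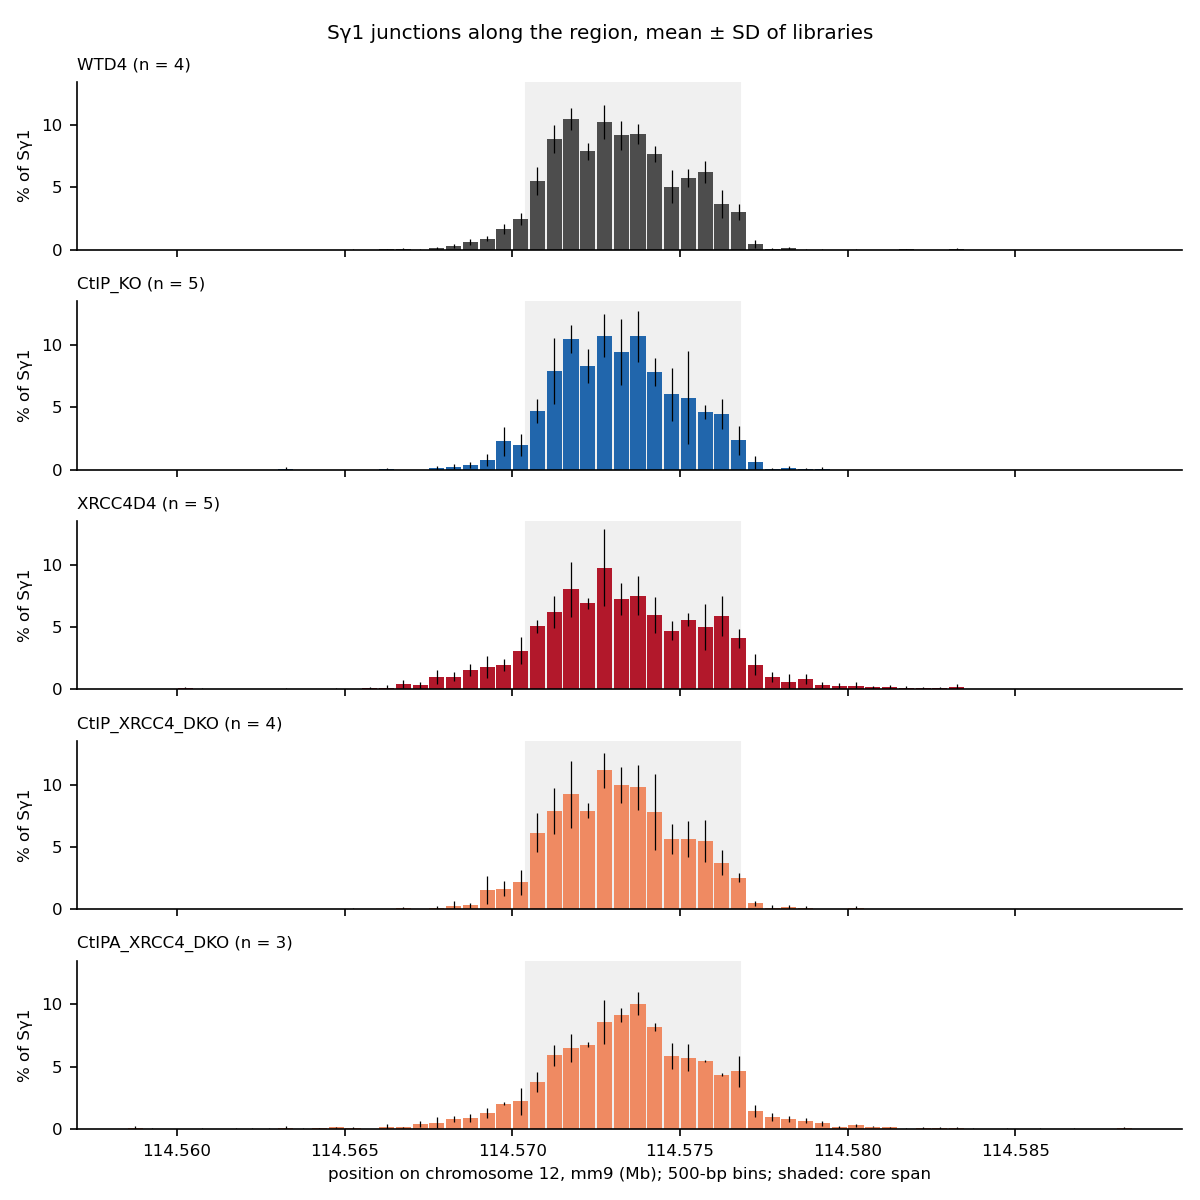
Percent of Sγ1 junctions per bin along chromosome 12 (mm9, Mb) in 5 day 4 groups, bars for the mean and lines for the SD of libraries, with the core span shaded. The part outside the core is 18.8% in XRCC4-deleted cells, 15.3% with the CtIPA allele and 7.13% in double-deleted cells.

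XRCC4-deleted cells with the CtIPA allele were compared with XRCC4-deleted day 4 cells. Overlaps averaged 2.84 ± 0.139 bp (SD, n = 3) against 2.86 ± 0.313 bp (SD, n = 5), a difference of -0.0226 bp (95% interval -0.514 to 0.466). The Sγ1 or Sε share was 52.8 ± 2.41% against 50.8 ± 5.06%, and the non-IgH share 13.8 ± 1.97% against 15.0 ± 4.57%. Sγ1 junctions outside the core were 15.3 ± 0.421% against 18.8 ± 4.39%, and inverted joins to Sγ1 18.1 ± 1.91% against 16.4 ± 4.51%. In the exact permutation test 0 of 4 primary and 0 of 14 secondary measures passed, and 0 of either had an unadjusted p under 0.05; the primary exact p-values ran from 0.143 to 0.893, and 8 libraries allow 0.0357 at the least. In 500 simulations of this comparison, effects were added to all 4 primary measures at once. The overlap effect of 1.24 bp was then called in 100% and the effect of 12.1 percentage points on the Sγ1 share outside the core in 98.2%. A single measure at the smallest exact p cannot pass the adjustment unless other measures are low too. These rates therefore do not cover an effect in 1 measure alone. The groups shared no sequencing run, so run and group cannot be told apart here.

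WT cells marked Ai differed from WT day 4 cells mainly in where junctions lay and in their orientation. In Ai cells the Sγ1 or Sε share fell from 73.6 ± 2.04% (SD, n = 4) to 48.3 ± 3.52% (SD, n = 4), a difference of -25.3 percentage points (95% interval -33.2 to -21.2). The Sε share fell from 36.9 ± 2.29% to 9.15 ± 2.57% and the Sμ share rose from 18.9 ± 1.54% to 36.6 ± 2.32%. Inverted joins rose from 24.9 ± 4.19% to 41.7 ± 6.16% in Sμ, from 7.96 ± 0.898% to 20.1 ± 2.87% in Sγ1 and from 5.11 ± 0.412% to 15.2 ± 1.71% in Sε. Junctions outside IgH rose from 6.65 ± 2.35% to 14.0 ± 2.26%. Overlap length was 1.72 ± 0.108 bp against 1.62 ± 0.0607 bp, a difference of 0.0930 bp (95% interval -0.0348 to 0.339, exact p = 0.143), while overlaps of at least 4 bp rose from 8.53 ± 0.897% to 10.7 ± 1.02% (exact p = 0.0286, adjusted p = 0.0571). Ai library 3 averaged 1.88 bp and the other Ai libraries 1.65 to 1.68 bp, so 1 library carried much of the difference in mean overlap.

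Both called primary measures had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p of 0.0571. Of 14 secondary measures 9 passed, 8 higher and 1 lower. The Sγ1 share outside the core differed by -1.62 percentage points (exact p = 0.171), and by 3.19 in the other direction with a core span holding 80% of junctions (exact p = 0.0286). The groups shared no sequencing run. Run 4 held 2 Ai libraries and the 2 WT CTV cultures, and the difference there depends on how the sorted fractions of a culture are weighted, which the labels do not give. With fractions weighted equally Ai minus culture was -12.6 percentage points for the Sγ1 or Sε share, -2.96 for the non-IgH share and 17.1 for inverted Sμ joins; with the junctions of a culture summed, so that fraction IV weighs most, it was -24.0, 6.21 and 23.4, and 2 against 2 allow no exact p below 0.333. Mean non-IgH counts were 202 in Ai and 190 in WT libraries against 1314 and 2918 junctions in IgH, and with the yield trend removed the non-IgH count was 1.42 times that of WT (exact p = 0.0571). Ai libraries 1 and 2 agreed within sampling noise in their counts over prey classes (chi-square p = 0.776), and shared 40 exact switch positions, where the density of sharing in the other 5 pairs of Ai libraries gives 24.1 to 27.8. Whether they came from 1 culture is not known, and they were kept as separate libraries. Averaged as 1 library, or without Ai library 1, 2 or 4 or WT library 1, 3 or 4, both calls ended. There 3 against 4 libraries allow no exact p below 0.0571 and only these 2 of the 4 primary measures reached it, whereas 3 did without Ai library 3 or WT library 2 and the calls stayed. Throughout, the Sγ1 or Sε difference stayed between -26.0 and -23.5 percentage points. Without Ai library 1 or 2 or WT library 1 no secondary measure passed.

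**Figure D4:**
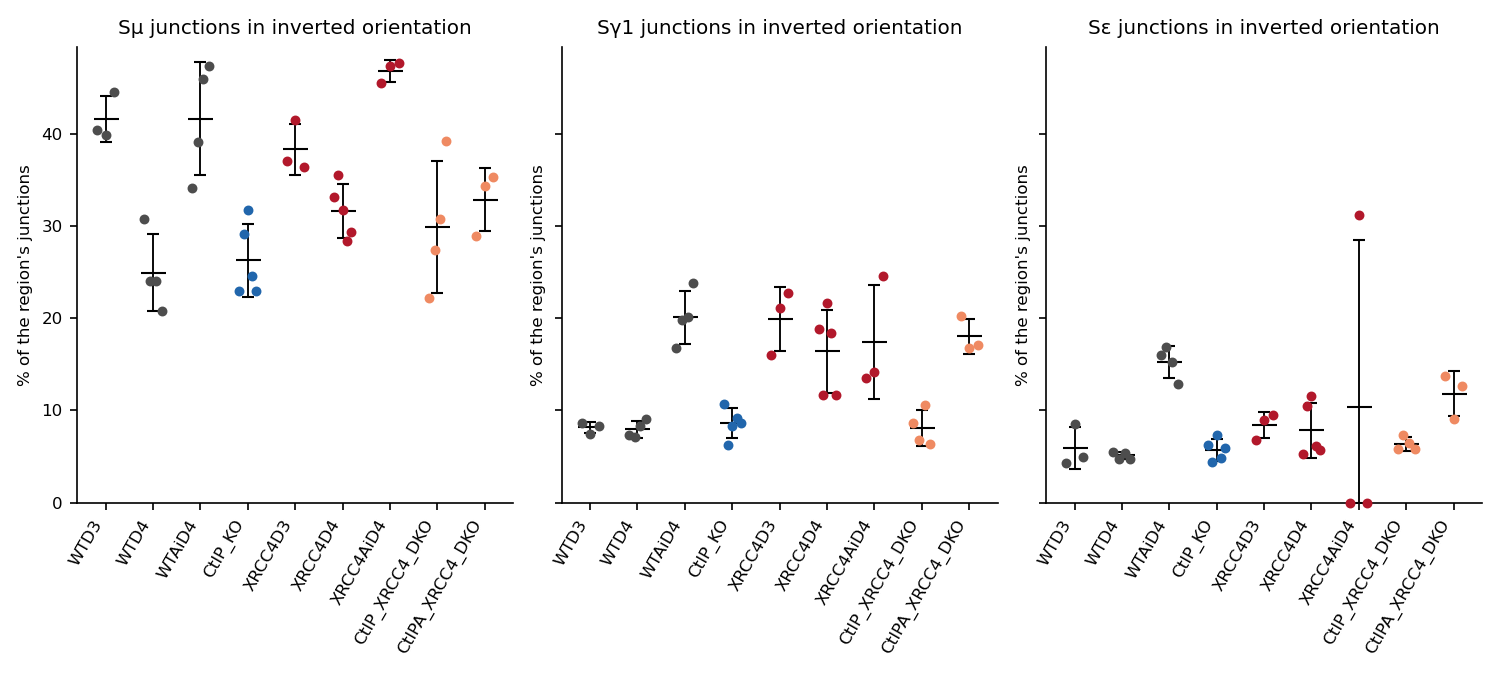
Percent of Sμ, Sγ1 and Sε junctions in inverted orientation per library in 9 groups, with points for libraries and bars for the mean and SD (lower bars end at 0). Inverted Sγ1 joins average 20.1% in WT cells marked Ai, 7.96% in WT day 4 and 16.4% in day 4 XRCC4-deleted cells.

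In XRCC4-deleted cells the Ai group was compared with the day 4 group without it. The Sγ1 or Sε share fell from 50.8 ± 5.06% (SD, n = 5) to 28.7 ± 7.99% (SD, n = 3), and the Sε share from 11.3 ± 4.48% to 1.80 ± 0.797%. Sγ1 junctions outside the core fell from 18.8 ± 4.39% to 10.5 ± 2.96%, and Sμ junctions outside theirs from 24.4 ± 7.00% to 6.89 ± 2.12%. Inverted Sμ joins rose from 31.7 ± 2.92% to 46.9 ± 1.20%, while inverted Sγ1 joins were 17.5 ± 6.20% against 16.4 ± 4.51%. The share outside IgH rose from 15.0 ± 4.57% to 30.3 ± 16.3%, with 48.9% in Ai library 3. Overlap length was 3.07 ± 0.225 bp against 2.86 ± 0.313 bp, a difference of 0.205 bp (95% interval -0.364 to 0.803).

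The Sγ1 or Sε share and the Sγ1 share outside the core had an exact permutation p of 0.0357 (adjusted p = 0.0714), and the non-IgH share 0.0714 (adjusted p = 0.0952). Of 14 secondary measures 7 passed, 2 higher and 5 lower. XRCC4-deleted Ai library 3 held 360 junctions, and the 3 Ai libraries held 13, 16 and 5 Sε junctions. Without library 3 the non-IgH difference was 5.95 percentage points (exact p = 0.190). Non-IgH counts averaged 167 with Ai and 213 without, against 485 and 1311 junctions in IgH, and with the yield trend removed the ratio was 1.25 (exact p = 0.464). Leaving out any 1 of the Ai libraries, or XRCC4-deleted library 2, 3, 4 or 5, ended the 3 primary calls, and leaving out any library at all left 0 secondary calls; 2 against 5 libraries allow no exact p below 0.0952. The groups shared no sequencing run. The Ai effect in XRCC4-deleted cells minus that in WT was -6.70 percentage points for the Sγ1 share outside the core (permutation p = 0.0503, adjusted p = 0.201), which passed with a core span holding 80% of junctions (-12.5, permutation p = 0.00416, adjusted p = 0.0166) or 95% (-5.11, permutation p = 0.0212, adjusted p = 0.0849), and the other 3 primary measures had an adjusted p of 0.612.

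In WT cells the share of junctions in Sγ1 or Sε was higher and the share outside IgH lower at day 4 than at day 3. The Sγ1 or Sε share was 61.7 ± 6.20% (SD, n = 3) at day 3 and 73.6 ± 2.04% (SD, n = 4) at day 4, the non-IgH share 18.7 ± 4.52% and 6.65 ± 2.35%, and the overlap 1.90 ± 0.137 bp and 1.62 ± 0.0607 bp. Each had an exact permutation p of 0.0571, the smallest possible here, so the design cannot reach 0.05, and an adjusted p of 0.0762; the 0 secondary calls of 14 (0 at an unadjusted p under 0.05) share that limit. With any library left out no exact p can fall below 0.1, so the calls could not be repeated there, and the differences stayed at -0.345 to -0.208 bp, 8.58 to 14.7 and -13.4 to -9.44 percentage points. With junctions in IgH as the denominator the Sγ1 or Sε gain was 3.11 percentage points (exact p = 0.229), and in the 1 run that held both days, with 1 library of day 3, the differences were 6.66 and -8.14 percentage points and -0.107 bp (exact p = 0.667, the smallest that 2 against 1 libraries allow). Non-IgH counts averaged 207 at day 3 and 190 at day 4 while junctions in IgH averaged 877 and 2918, so the lower share came with more IgH junctions, and with the yield trend removed the day 4 to day 3 ratio was 0.615 (exact p = 0.171).

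XRCC4-deleted cells at day 4 had a Sγ1 or Sε share of 50.8 ± 5.06% (SD, n = 5) against 43.2 ± 0.709% (SD, n = 3) at day 3, and a non-IgH share of 15.0 ± 4.57% against 24.3 ± 3.73%. Overlap was 2.86 ± 0.313 bp against 2.97 ± 0.242 bp. By the exact permutation test 0 of 4 primary measures passed (1 at an unadjusted p under 0.05, the Sγ1 or Sε share with p = 0.0357 and adjusted p = 0.143) and 0 of 14 secondary ones (1 at an unadjusted p under 0.05). For 5 against 3 libraries 0.0357 is the smallest exact p, and 1 measure alone at it cannot pass the adjustment. The ranges of the groups did not overlap in the Sγ1 or Sε share. Within run 2 the differences were 6.49 percentage points for the Sγ1 or Sε share (exact p = 0.2), -7.48 for the non-IgH share (exact p = 0.4) and 0.00933 bp for overlap (exact p = 1). With the yield trend removed the day 4 to day 3 ratio of non-IgH counts was 0.679 (exact p = 0.107). The day effect in XRCC4-deleted cells did not differ detectably from that in WT cells in any primary measure (permutation p from 0.356 to 0.510).

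Across CTV fractions I to IV of WT cells the share of junctions in the switch regions rose and the share outside IgH fell, as IgH junctions increased. The Sγ1 or Sε share averaged 37.3 ± 7.77% (SD, n = 2) in fraction I, 51.3 ± 6.07% in II, 70.9 ± 0.201% in III and 77.6 ± 0.822% in IV. The non-IgH share averaged 40.6 ± 4.60%, 17.0 ± 2.70%, 6.21 ± 0.150% and 3.57 ± 0.260% in the same order, and the Sε share rose from 14.0 ± 3.36% to 40.5 ± 3.33%. The slopes were 14.0 and -12.2 percentage points per fraction, with the same sign in both cultures, each with an exact p of 0.00347 after permuting fractions within culture, the smallest of 576 orders, and an adjusted p of 0.00694. Overlap (0.0215 bp per fraction, exact p = 0.493) and the Sγ1 share outside the core (0.253 percentage points, exact p = 0.611) did not pass. Of the secondary measures Sε rose by 8.91 and overlaps of at least 4 bp by 1.05 percentage points per fraction (adjusted p = 0.0972 by the exact permutation test). Without the fraction I libraries of 283 and 402 junctions the slopes were 13.1 and -6.70 and both calls ended, with an exact p of 0.0556, the smallest that the remaining orders allow. Junctions outside IgH numbered 124 and 150 in fraction I and 131 and 169 in fraction IV, while junctions in IgH numbered 159 and 252 against 3361 and 4826. All 8 libraries came from 1 run.

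Outside IgH, lists of junctions for 27 libraries held 5050 junctions in 3513 bins of 100 kb. The bin with junctions in the most libraries was chromosome 7 from 132600001 to 132700000 (mm9), with 76 junctions in 24 libraries, and the next bin, to 132800000, held 35 in 18. Chromosome 6 from 70600001 to 70700000 held 47 junctions in 18 libraries, chromosome 2 from 98500001 to 98600000 held 43 in 18, and chromosome 6 from 122500001 to 122600000 held 26 in 17. On chromosome 12 outside IgH, 63300001 to 63400000 held 35 junctions in 16 libraries, 70300001 to 70400000 held 39 in 16 and 70200001 to 70300000 held 26 in 15. Chromosome 15 from 103100001 to 103200000 held 59 junctions in 15 libraries, of which 46 lay at position 103140488 and 27 came from XRCC4-deleted Ai library 3, and chromosome X from 131700001 to 131800000 held 20 in 13, of which 15 lay at 131795958. Gene annotation of these loci was not used here.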

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

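All tests of explanations in this part were chosen only after the results were seen; the tests of the difference between effects were planned. The yield test is a second version: a first one, which assumed a fixed number of background junctions per library, was replaced once it had given the slope of 0.380 printed below. The limits used for joins with long overlaps or insertions, and the test of run for Ai cells, were also revised after their values were seen.

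The effect of CtIP deletion differed between cells with and without XRCC4 by -1.08 bp in overlap length, by 23.6 percentage points in the Sγ1 or Sε share and by -11.3 in the Sγ1 share outside the core. Sequencing run as the source is argued against by the difference in overlap within runs that held both groups, -1.10 bp against a pooled SD of 0.248 bp. A mixture with cells that kept XRCC4 stays open and could give the same values. The share of XRCC4-type junctions estimated from 6 measures ran from -6.57% to 14.9%. It was 13.2% (95% bootstrap interval 3.02 to 23.2) for overlap length and 10.4% (6.05 to 15.7) for overlaps of at least 4 bp. For the Sγ1, Sμ and Sε shares outside their cores and for inverted Sγ1 joins the intervals included 0, the widest being -44.3 to 20.4 for inverted Sγ1 joins. In that share 0 of 15 pairs of measures differed. Intervals this wide could hardly differ, so that count does not argue for a mixture. Libraries of CtIP-deleted cells under this name cannot be told apart from double-deleted ones by overlap length (0.157 bp longer, exact p = 0.0794), although overlaps of at least 4 bp were more frequent, 10.4% against 8.79% (exact p = 0.0159, adjusted p = 0.111 over 7 measures). A need for CtIP in joining without XRCC4, which the design addresses, was not tested apart from these, because loss of the XRCC4 protein is not measured in these data.

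The non-IgH share was higher in XRCC4-deleted and CtIP-deleted than in WT day 4 libraries, which held more junctions. Within groups the non-IgH count grew more slowly than the IgH count, with a slope of 0.380 on log scales (95% bootstrap interval 0.166 to 0.620), so a low yield alone could raise the share. With that trend removed the non-IgH count stayed 1.48 times (exact p = 0.0794) and 1.66 times (exact p = 0.0635) that of WT, and at the bounds of the slope the ratios were 1.24 (exact p = 0.349) to 1.82 (exact p = 0.0317) and 1.31 (exact p = 0.254) to 2.16 (exact p = 0.0317), so yield stays open for both groups. Joins with long overlaps or insertions, which made up 26.3% of non-IgH and 3.03% of Sγ1 junctions, are argued against as the whole source in both groups: without them the differences were 6.87 percentage points (pooled SD 2.97, exact p = 0.0159) in XRCC4-deleted and 11.4 (pooled SD 6.04, exact p = 0.0317) in CtIP-deleted cells. A true rise in joins outside IgH also stays open.

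WT cells marked Ai held more inverted Sγ1 joins, and shared no run with WT day 4 libraries. Run alone is argued against, since both Ai libraries of run 4 (20.2% and 23.8%) lay above all 8 WT CTV libraries of that run (1.75% to 8.82%), which are sorted fractions of 2 cultures, and 15.4 percentage points above the 2 culture means (pooled SD 1.90; 2 against 2 allow no exact p below 0.333). In that run Ai minus culture was -15.2 for the Sε share (pooled SD 3.47), with both Ai libraries below all 8 fractions, while for the Sγ1 or Sε share it was -12.6 (pooled SD 4.41) with fractions weighted equally and -24.0 (pooled SD 3.70) with junctions summed, and for the non-IgH share -2.96 (pooled SD 3.02) and 6.21 (pooled SD 2.76), and since the mix of fractions in a culture is not known and both lie inside the spread between fractions, run stays open for these 2. Inverted Sμ joins of the Ai libraries in that run (46.0% and 47.4%) lay inside the range of the 8 fractions (18.3% to 50.7%), so run stays open for them too. Inverted joins with long overlaps or insertions made up at most 0.456% of Sγ1 junctions in an Ai library, too few for a difference of 12.2 percentage points. Background joins with short overlaps and differences between cultures were not tested and stay open, as does an effect of Ai on the orientation of joins.

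Of 90 combinations of a group of 4 or 5 libraries and a measure, 5 had a library far from the others, where chance gives about 4.5, or 1 in 20. WT day 4 library 1 had a non-IgH share of 10.1%, the others 5.10% to 5.89%. WT Ai library 3 had a mean overlap of 1.88 bp against 1.65 to 1.68 bp and a Sγ1 share outside the core of 8.49% against 3.62% to 4.43%. WT Ai library 4 had a Sγ1 or Sε share of 43.1% against 49.8% to 50.3% and a Sε share of 5.33% against 9.98% to 10.8%.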

How the results depend on the processing

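The replicate-averaging and long-overlap settings were chosen only after the data were seen. The 871 alternative values include counts of secondary calls and 32 values from the authors' pooled tables, which have no test. Of the 871, 702 stayed with the main result. These kept direction and side of the threshold, had a similar count of secondary calls, or were pooled values close to the main ones. Another 125 lost a call or had fewer secondary calls, and 13 gained a call or had more. A further 29 reversed, and 2 pooled values moved away from the main ones. Unless the construction shows it (fewer libraries, another denominator), the cause was not tested. All 4 primary calls of XRCC4-deleted against WT cells, and the overlap and Sγ1-core calls of double-deleted cells, held under the settings run for them, the replicate block excepted. CTV fractions were added as controls for CtIP-deleted cells only, not for XRCC4-deleted cells. Removal of the yield trend left the XRCC4-deleted non-IgH count at an exact p of 0.0794.

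Replicate block. Outside CtIP-deleted cells the shared numbers did not all correlate above 0.1, and 3 or 4 pairs allow no p below 0.25 or 0.125, so every call ends. XRCC4-deleted against WT gave 1.34 bp, -24.4, 12.7 and 9.53 percentage points; CtIP-deleted -13.1 and 16.0; double-deleted -1.13 bp, 14.6 and -12.3; WT Ai -25.3 and 7.35; XRCC4-deleted Ai -0.0140 bp (reversed), -20.7, -10.5 and 13.7; WT days -0.282 bp, 12.2 and -11.8; XRCC4-deleted days 0.110 bp (reversed). In these other comparisons 0 to 3 libraries correlated best with their own number. The 3 were all the numbers shared by the WT days, with correlations of 0.0668 to 0.537, so a pairing there is not excluded.

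Within runs CtIP-deleted cells gave -0.000316 bp, -5.80 and 8.67, WT days -0.107 bp, 6.66 and -8.14, and XRCC4-deleted days 0.00933 bp. With at least 500 junctions XRCC4-deleted Ai gave -17.6, -9.999 and 5.95 with 0 secondary calls, CTV slopes 13.1 and -6.70, and the Ai interaction on the non-IgH share -1.41. IgH denominators gave -0.643 (CtIP-deleted) and 3.11 (WT days). Without Sμ, double-deleted cells gave 3.55 (Sγ1 or Sε) and -0.547 (non-IgH), the Ai interaction -10.3 and the CtIP interaction -15.9 (non-IgH, a call gained). With all WT day 4 controls, the CTV fractions of 2 cultures counted as separate libraries, CtIP-deleted cells lost both calls, at -0.980 and 6.26. They gave 0.913 (Sγ1-core, reversed). Insertions as 0 gave -0.0378 bp (CtIP-deleted). On the log scale the CtIP interaction on the non-IgH share gained a call at -1.06.

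Overlaps of at least 2 bp gave 1.48 (CtIPA) and -5.31 points (WT days); at least 6 bp 1.29 (WT Ai), 0.167 (XRCC4-deleted days) and -0.318 (CTV). An 80% core gave 3.19 (WT Ai), -1.78 (CTV) and -12.5 (Ai interaction); a 95% core -0.307 and -5.11 for the last 2, the interaction gaining a call under both; the downstream side 0.177 (WT days). Without long overlaps CtIPA non-IgH was 0.151. Both genotypes together gave -4.87 for the Ai Sγ1-core share. WT Ai gave -25.8 and 7.31 with libraries averaged, -26.9 and 7.21 with libraries 3 and 4, and 0.218 bp and 0.325 in the pooled tables.

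Leaving out 1 library gave these ranges. CtIP-deleted: -13.1 to -6.64 and 10.3 to 16.0. Double-deleted: 9.75 to 15.8 and -1.02 to 5.50 (non-IgH). CtIPA: -0.120 to 0.0604 bp and -2.40 to 0.651 (non-IgH). WT Ai: 0.0394 to 0.116 bp, -26.0 to -23.5, -2.75 to -1.13 (Sγ1-core), 6.49 to 8.52 and 0 to 9 secondary calls. XRCC4-deleted Ai: -24.7 to -17.6, -9.999 to -6.67, 5.95 to 21.0 and 0 secondary calls. WT days: -0.345 to -0.208 bp, 8.58 to 14.7, -1.39 to 0.586 and -13.4 to -9.44. XRCC4-deleted days: -0.210 to 0.0249 bp. CTV: -0.00416 to 0.0583 bp and -0.118 to 0.821 (Sγ1-core). Ai interaction: -8.38 to -5.05 (Sγ1-core) and -1.41 to 13.6 (non-IgH). CtIP interaction, non-IgH: -14.1 to -7.54. Libraries of 283 to 402 junctions limit fraction I and XRCC4-deleted Ai library 3.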

Other observations

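All tests in this part were chosen only after the values were seen; 48 tests of overlap length by prey were run and adjusted together.

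The longer overlaps of XRCC4-deleted cells were not alike at both switch regions. At Sγ1 the mean overlap was 3.09 ± 0.245 bp (SD, n = 5) against 1.70 ± 0.0548 bp (SD, n = 4) in WT, and at Sε 2.04 ± 0.287 bp against 1.54 ± 0.0652 bp. The hypothesis that the lengthening is greater at Sγ1 was tested on the Sγ1 minus Sε difference per library, which was 1.06 ± 0.186 bp against 0.156 ± 0.0333 bp (exact permutation p = 0.0159, adjusted p = 0.0544). The difference within Sγ1 alone, 1.39 bp, argues against a shift of prey from Sε to Sγ1 as the whole source of the longer mean. Part of the longer mean can come from that shift. Sγ1 held 77.9% of Sγ1 and Sε junctions in XRCC4-deleted cells against 49.8% in WT. How large that part is was not tested. Deletional joins within Sμ lengthened as well, from 1.57 ± 0.0466 bp to 2.75 ± 0.161 bp (exact permutation p = 0.0159, adjusted p = 0.0544, n = 5 and 4), and averaged 1.86 ± 0.128 bp in WT cells marked Ai (exact permutation p = 0.0286 against WT, adjusted p = 0.0914, n = 4 and 4).

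Inverted Sμ joins recurred at single positions. Of 5293 such junctions 159 lay at position 114664836 of chromosome 12 (mm9), in 41 libraries, and 141 at 114664951, in all 42. The most used positions held 43 of 11609 deletional Sμ junctions, 32 of 22125 deletional Sγ1 junctions and 105 of 16346 deletional Sε junctions. Overlaps of inverted Sμ joins averaged 2.55 ± 0.413 bp (SD, n = 4) in WT day 4 cells and were longer both in CtIP-deleted cells, 3.51 ± 0.383 bp (SD, n = 5), and in XRCC4-deleted day 4 cells, 3.32 ± 0.161 bp (SD, n = 5), each with an exact permutation p of 0.0159 (adjusted p = 0.0544). They averaged 3.17 ± 0.750 bp in double-deleted cells (n = 4), 4.43 ± 0.575 bp in WT day 3 cells (n = 3), and 5.46, 5.12, 3.51 and 2.57 bp in CTV fractions I to IV (n = 2 each). Of all inverted Sμ junctions 9.77% over all libraries had an overlap of at least 10 bp or an insertion over 10 bp. In single libraries the share ran from 0% to 22.0%, with a median of 9.97%.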
